A study of Mus musculus with 4 samples.

How the data were processed

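RNA from the CA1 field of the hippocampus was hybridised to 4 arrays with 2 dyes, 1 for each time after conditioning (1, 2, 4 and 6 h). Per the labels, the MK sample was labelled with Cyanine-3 (green) and the MK C+S sample with Cyanine-5 (red) on every array, with no dye swap. How many animals gave the RNA of an array is not given in the sources used here. Samples were grouped by time as the labels give it.

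The deposited values are log ratios per spot, and log10 was assumed for them, since the deposited table and the labels do not state a base. The range of the values, from -3.10 to 1.58 over the 4 arrays, was the basis of that reading. Scale, centring method and direction all stay unknown. The median of each deposited column was 0 at 1, 2, 4 and 6 h, with exact zeros included. Scanner, extraction software, background correction and normalization by the authors are not given in the sources used here. No intensities were used here, so signal over background, saturation and dye curves could not be examined.

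The table had 16281 spots. Exact zeros made up 22.7% of spots at 1 h, 9.34% at 2 h, 7.39% at 4 h and 10.0% at 6 h, and 621 spots were 0 on all 4 arrays. An exact 0 was read as no measured ratio. The median of the remaining spots (0.0055, -0.00038, 0.00073 and -0.0054 at 1, 2, 4 and 6 h) was subtracted from each array. A platform annotation named 13738 spots with 1 gene and 52 with several, and 2491 were unnamed here. Spots with several genes or none were left out of gene values. Entrez identifiers of 13694 spots matched the RefSeq gene table (assembly GRCm38.p6, used for names only), which changed 0 symbols. A gene's value was the mean of its measured spots. The annotation named 10699 genes, of which 10623 had a value on at least 1 array and 8552 on all 4. The pooled SD between spots of a gene was 0.225, 0.204, 0.168 and 0.329 at 1, 2, 4 and 6 h.

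Genes at each time were counted at a size of 2-fold or more, which is 0.301 log10 units, with no p-value. The mean over the 4 times and the slope on hours were tested with lmFit and eBayes in limma 3.58.1 (R 4.3.3, statmod 1.5.0), two-sided, with Benjamini-Hochberg adjustment at 0.05, on genes with a value on all 4 arrays. The error in these tests is the spread between times, since no time has a replicate. Tests had been set out for log2 values, and the change of log base leaves their p-values as they are.

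The 27 gene lists were fixed before the data were examined. They covered activity-regulated, synaptic, signalling, chromatin, stress, metabolic and protein turnover genes and markers of the cell types and neighbouring regions that a CA1 sample can hold. Each list's median on each array was placed among 10000 random lists of the same size, which were not matched on expression because no intensities were used. Lists were tested in the mean and the slope with camera at its preset correlation of 0.01, adjusted over the 27 lists, and again with an estimated correlation and with fry. Further lists of choroid plexus, leptomeningeal, ependymal and abundant brain transcripts were written later, for patterns seen in the data.

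Named genes followed a rule fixed before the data were examined, except where the text says otherwise. The rule took the 4 highest and 4 lowest genes per time among those with a value on all 4 arrays. It took the 10 highest and 10 lowest means among genes with the same sign on all 4 arrays, and the 4 most positive and 4 most negative slopes by moderated t. It also took up to 4 members per list with the largest absolute mean, and Fos, Egr1, Arc, Junb and Nr4a1. Members of the choroid plexus list at 1 h beyond the rule were named after their values were seen.

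The tests were checked on simulated data with 8552 genes. In the mean, 18 of 100 genes shifted by 0.3 log10 units and 92 of 100 shifted by 0.6 were called, with 9 unchanged genes called. For the slope, the simulated size was the whole change from 1 to 6 h in log10 units, not a change per h. At a size of 1.2, 64 of 100 genes were called, and at 2.4, 98 of 100, again with 9 unchanged genes. A list of 20 genes shifted by 0.15 gave an adjusted p of 1.2e-06 in camera, and 0 unshifted lists were called. The simulated genes were independent of each other, so this check does not show how often camera calls unshifted lists of correlated genes.

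Alternatives set before the data were examined covered the size threshold, centring, the summary of spots, scaling between arrays, array weights, filters, the time covariate, the list test and leaving out each array. Added later were exact zeros kept as a ratio of 1, base-2 and natural logs, removal of a running median over 51 neighbouring spots, camera on ranks and fry for the slope, lists from the median of a gene's spots, estimated correlations for lists passing only under an alternative, and named gene means without each array. The comparison of different spots of a gene was also chosen after the data were seen. Correlations between arrays were taken across genes, with bootstrap intervals over genes. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.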

Results

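Gene expression in the CA1 field of the mouse hippocampus, a layer of pyramidal neurons needed for contextual memory, was compared between mice given MK-801 alone (MK) and mice given MK-801 before contextual fear conditioning (MK C+S). MK-801 blocks the NMDA type of glutamate receptor. The animals were young males of the inbred strain C57BL/6J, and the labels give the dose as 300 micrograms per g body weight. That value lies far above the doses usually given to mice and is printed as labelled, so the dose actually used is uncertain. In the MK C+S group the drug preceded conditioning by 1 h. Conditioning consisted of 2 min in an unfamiliar chamber and a foot shock of 1 s at 0.5 mA, with the sequence given 3 times. RNA was taken 1, 2, 4 and 6 h after the last shock, and 1 array with 2 dyes was used at each time, with MK in the green channel and MK C+S in the red. All 4 arrays had this dye orientation, so a dye effect and an effect of conditioning were confounded. No time had a replicate array, so values at a single time carry no error, and the number of arrays limits the precision.

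The deposited values were log ratios. A positive value likely means more RNA in MK C+S than in MK, by the usual order of red over green, but the direction is not stated. Fold values assume base-10 logs, which the labels do not state either. Spots with a ratio numbered 12586, 14760, 15078 and 14650 at 1, 2, 4 and 6 h, and they covered 9162, 10151, 10313 and 10102 named genes. Most genes rested on 1 spot. The correlation between spots of the same gene on the same array was low, with a Spearman value across pairs of spots of 0.0741 at 1 h, 0.0615 at 2 h, 0.127 at 4 h and -0.0497 at 6 h. Most values named here have no second spot to check them.

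At 1 h, genes of the choroid plexus, the epithelium that makes cerebrospinal fluid, stood out with positive log ratios. Kcne2, a potassium channel subunit, was at 0.71, Sostdc1, a secreted inhibitor of BMP and Wnt signals, at 0.66, and the growth factor Igf2 at 0.54. The folate receptor Folr1 was at 0.49, Igfbp2 at 0.45 and the water channel Aqp1 at 0.40. Of the 8 measured genes in the fixed list of choroid plexus and ependyma markers, 7 were positive and 6 passed 2-fold. The list median was 0.47, at percentile 100 of 10000 random lists of the same size. Kl was the exception at -0.24, as the mean of 3 spots at 0.49, 0.71 and -1.91. Ttr, the most abundant choroid plexus transcript, had no ratio at 1 h, and its later values were -0.66, -1.27 and -0.12.

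Immediate early genes, which neurons switch on within minutes of activity, lay below 0 at 1 h. Of 27 measured, 17 were negative, and the list median of -0.087 was at percentile 0.37 of random lists. The transcription factor gene Egr1 was at -0.44, Klf4 at -0.44, and the dendritic protein gene Arc at -0.19. Fos, Junb and Nr4a1 were close to 0, at -0.040, 0.00029 and 0.057. Ribosomal protein genes also had a negative median (-0.059, percentile 0.98, 31 of 44 negative). Negative medians outside the central 95% of random lists were found as well for cholesterol synthesis (-0.12, with Sqle at -0.33), presynaptic vesicle genes (-0.085, with the fusion ATPase Nsf at -0.26), endothelial and mural cell markers (-0.085, with the tight junction gene Cldn5 at -0.46) and CA3 pyramidal cell markers (-0.11). The CA3 median fell inside, at percentile 8.84, with a running median over neighbouring spots removed.

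Single genes with the highest 1 h values were the hydrogen peroxide enzyme Cat (1.57, or 37.4-fold), Ecrg4 (1.501), Sys1 (1.05) and Krtap14 (0.99). Ecrg4 encodes a secreted peptide precursor known from choroid plexus. The lowest were Xist (-2.63), Pgpep1 (-2.12), 4930522H14Rik (-1.9997) and Cyp4b1 (-1.70). Xist, the RNA that silences an X chromosome in females, was measured here in males by 2 spots that differed. The spot behind the 1 h value gave -2.63, -1.44 and -0.68 at 1, 2 and 6 h, and the other gave 0.018, 0.15 and 0.054 at 2, 4 and 6 h. The spot behind Pgpep1 at 1 h gave -2.30 at 6 h, where its other spot gave 0.87. In all, 776 genes differed by 2-fold or more at 1 h, 469 of them positive and 307 negative. The positive share was 60.4%, against 43.5% of genes past 2-fold with natural logs and 13.6% with base-2 logs. It was 52.8% at 1.5-fold, and the majority turned to negative among genes with 2 or more spots, with 39.5% positive.

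At 2 h the immediate early genes lay on the other side of 0. Egr4 was at 0.50, Egr2 at 0.44, Arc at 0.38, Egr1 at 0.31 and Fos at 0.15, and 21 of 30 measured were positive. Egr4 is named here after its value was seen. The list median of 0.056 was at percentile 96.8, inside the central 95% of random lists, while the list mean of 0.097 was at percentile 99.99. Heat shock and chaperone genes had a median of 0.072 (percentile 99.4, 25 of 35 positive), with the small chaperone Cryab at 0.38. Astrocyte markers had a median of 0.091 (percentile 98.8), with the glycolytic enzyme Aldoc at 0.29 and the intermediate filament gene Gfap at 0.13.

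Negative medians at 2 h were found for endothelial and mural markers (-0.13, percentile 0.16, 15 of 19 negative), with Cldn5 at -0.81, the transporter Slco1a4 at -0.36 and the VEGF receptor Kdr at -0.32. CA3 markers were at -0.21 (percentile 0.10). Ribosomal protein genes were at -0.075 (percentile 0.12, 35 of 52 negative) and oxidative phosphorylation genes, which encode the respiratory chain, at -0.071 (percentile 0.40, 32 of 45 negative). Proteasome subunits were at -0.072 (percentile 1.01), with Psmd13 at -0.38.

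The lowest single genes at 2 h were the carbonic anhydrase Car1 (-2.66), the bile acid transporter Slc10a2 (-1.98), the thyrotropin-releasing hormone receptor Trhr (-1.52) and Diablo (-1.30), a mitochondrial activator of apoptosis. The Trhr value was the mean of spots at -3.10 and 0.059. The highest were Tnfrsf25 (0.82), the endothelial transcription factor Sox17 (0.81), Cyp2j5 (0.75) and Zfp275 (0.67). A 2-fold difference was reached by 668 genes, 248 positive and 420 negative. The positive share of 37.1% was 5.08% with natural logs and 0% with base-2 logs. It was 46.5% at 1.5-fold and 17.6% at 3-fold, and 11.9% among genes with 2 or more spots.

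At 4 h immediate early genes had a positive median of 0.080 (percentile 99.7, 19 of 30 positive). Arc was at 0.52, the transcription factor gene Srf at 0.38 and Junb at 0.27, while Egr1 and Fos were close to 0, at -0.0080 and -0.054, and Klf4 was at -0.37. Ribosomal protein genes had a positive median of 0.072 (percentile 99.97, 39 of 55 positive) and oxidative phosphorylation genes of 0.059 (percentile 99.2, 30 of 47 positive). Cytoskeleton and adhesion genes were at 0.086 (percentile 99.9), with the neurofilament gene Nefh at 0.17, and microglia markers at 0.090 (percentile 99.1), with the complement gene C1qb at 0.23. CA3 markers were negative in 8 of 8 genes, with a median of -0.36 at percentile 0. Endothelial and mural markers were negative in 16 of 19, with a median of -0.11 at percentile 0.54.

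Single genes with the lowest 4 h values were Car1 (-2.21), Cat (-1.92), the synaptic vesicle gene Vamp1 (-1.78) and the extracellular matrix gene Fbln2 (-1.58). Cat had been the highest gene at 1 h. The highest were Phlda3 (1.03), the ribosomal gene Rpl35a (0.91), the RNA-binding protein gene Hnrnpl (0.86) and the reelin adaptor Dab1 (0.85). A 2-fold difference was reached by 729 genes, 257 positive and 472 negative. The positive share of 35.3% was 12.3% with natural logs and 4.35% with base-2 logs. It was 45.6% at 1.5-fold and 20.8% at 3-fold.

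At 6 h the spread was wider, and few gene groups stood apart. Ribosomal protein genes kept a positive median (0.073, percentile 99.1, 36 of 51 positive), microglia markers were at 0.11 (percentile 98.2) with Fcer1g at 0.29, and CA3 markers at -0.18 (percentile 2.17) with Plagl1 at -1.13, the mean of spots at -2.19 and -0.058. By the list mean all 3 fell inside the central 95% of random lists, at percentiles 93.9, 88.2 and 3.24. With a running median over neighbouring spots removed, the microglia median was at percentile 95.9 and the CA3 median at 8.49. The immediate early gene median was -4.7e-05, with 15 positive and 15 negative, although Egr2 was at 0.86. Arc was at 0.18, Egr1 at -0.29, Fos at 0.0036, Junb at 0.025 and Nr4a1 at 0.030.

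The lowest genes at 6 h were the ephrin receptor Epha3 (-2.23), the neuronal splicing factor Nova1 (-2.12), Lce1a2 (-1.79) and Ttc25 (-1.68). The highest were Olfr894 (0.99), Chac1 (0.97), the neuronal transcription factor Atoh1 (0.96) and Ighv7-1 (0.95). A 2-fold difference was reached by 2211 genes or 21.9% of those measured, against 8.47%, 6.58% and 7.07% at 1, 2 and 4 h. Of these, 1028 were positive and 1183 negative, a positive share of 46.5% that was 7.53% with base-2 logs. The majority turned to positive, at 64.5%, among genes with 2 or more spots, and was 50.5% with each spot on its own. The median absolute deviation of the spots was 0.217 at 6 h, against 0.153, 0.153 and 0.148 at the earlier times. Same-gene spots were weakly anticorrelated at 6 h (Spearman -0.0497, 95% interval -0.0920 to -0.00484), and the 77 genes whose 2 or more spots all passed 2-fold the same way compared with 84.2 after shuffling spots among genes.

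**Figure D1:**
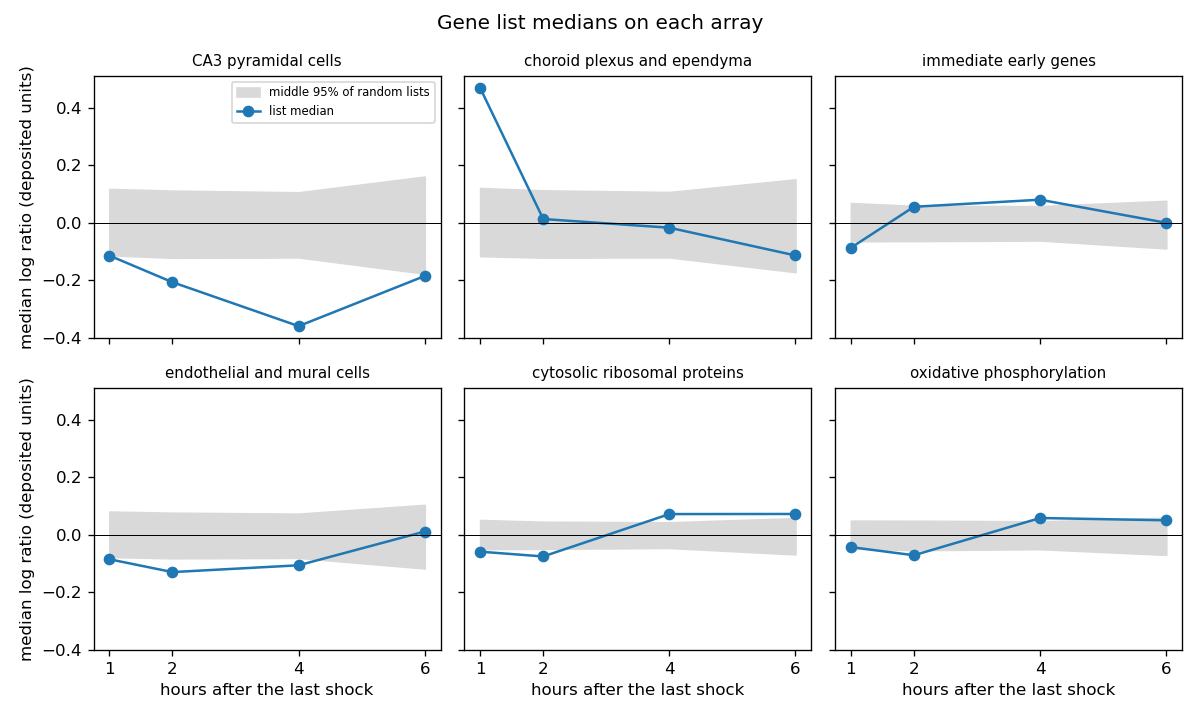
Median log ratio in deposited units (vertical axis) against hours after the last shock (horizontal axis) for 6 fixed gene lists. Points are list medians on the 1 array at each time, and the grey band holds the central 95% of medians of 10000 random lists of the same size. The choroid plexus and ependyma median was 0.47 at 1 h, and the CA3 median reached -0.36 at 4 h.

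**Figure D2:**
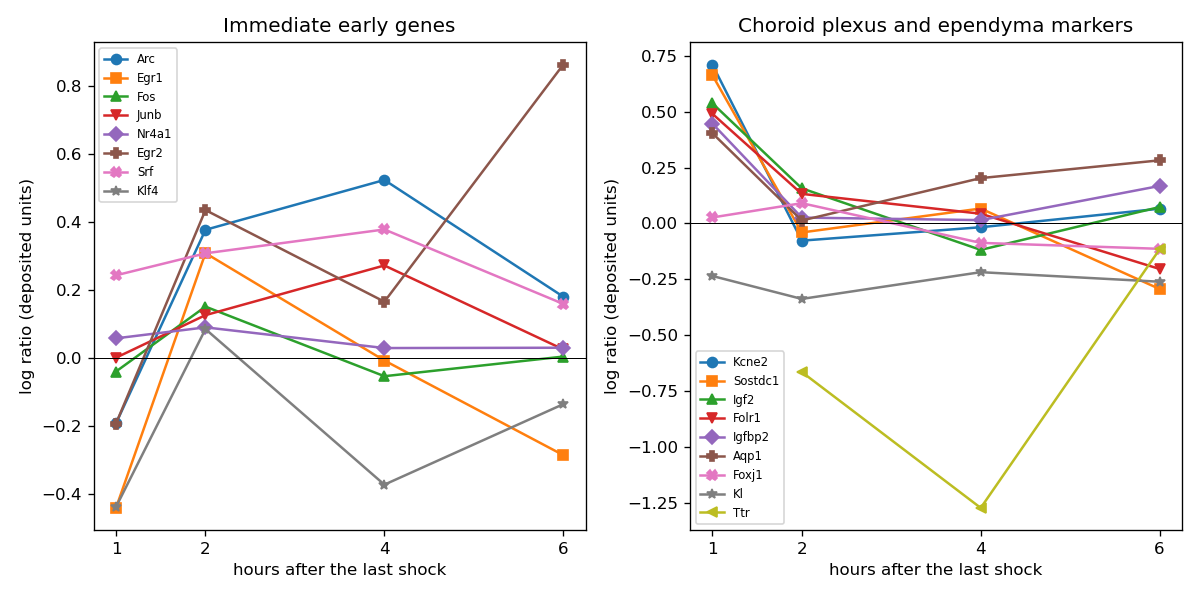
Log ratio in deposited units against hours after the last shock for named immediate early genes (left) and for the measured choroid plexus and ependyma markers (right). Each point is a gene's mean over its spots on 1 array. Egr1 was at -0.44 at 1 h and 0.31 at 2 h, and Kcne2 was at 0.71 at 1 h.

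Of 108 list medians computed over the 27 lists and 4 times, 24 fell outside the central 95% of random lists, 10 above and 14 below. By chance 5.4 would, if the genes of a list were no more correlated than random genes. List members that vary together would raise that number, and the same lists recur on correlated arrays. The excess is therefore not a count of real shifts. These percentiles describe single arrays and are not tests across animals. With the list mean in place of the median, 18 fell outside, 13 of them shared. Medians at the earlier times whose list mean lay inside were CA3, endothelial and presynaptic genes at 1 h (percentiles of the mean 3.56, 2.85 and 4.20) and astrocyte and oxidative phosphorylation genes at 2 h (96.9 and 7.07). At 4 h they were cytoskeleton, microglia and oxidative phosphorylation genes (96.96, 95.7 and 96.97).

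Averaging over the 4 times asked which genes differed between MK C+S and MK whatever the time, with the spread between times as the error. As all arrays had 1 dye orientation, a dye or spot effect shared by them gives the same result. The mean cannot tell such an effect from one of conditioning. The highest means among genes with the same sign on all 4 arrays were 3110082I17Rik (0.57, SD 0.045, n = 4 arrays) and Mrps24, a mitochondrial ribosomal protein gene (0.56, SD 0.024). They were followed by the glucose transporter Slc2a2 (0.43), the aminopeptidase Lvrn (0.40), Prss39 (0.40), Lsm14a (0.40), Gm16982 (0.39), the neural transcription factor Pou3f4 (0.39), the thyroid hormone activating enzyme Dio2 (0.39) and Xlr3a (0.37). The lowest were Car1 (-1.52), Fbln2 (-1.04), Adssl1 (-0.79), the N-type calcium channel gene Cacna1b (-0.79), the neuronal adhesion gene Cntnap4 (-0.77) and Ccdc80 (-0.77). Fcgr2b, an inhibitory antibody receptor, followed at -0.72, the mean of a spot between -2.01 and -0.49 and another between -0.59 and -0.059 over the times, with Mcts1 at -0.68, Speer4d at -0.67 and Prxl2c at -0.66. Spots of Car1, Fbln2, Adssl1 and Cacna1b and the Fcgr2b spot that reached -2.01 had close numbers, between 15631 and 15871. Near them, between 15629 and 15873, lay the spots of Cyp4b1, Slc10a2 and Crisp3 and the Trhr spot that reached -3.10. Not every spot there was low, as Nr4a1 at spot 15733 lay between 0.029 and 0.090. An effect tied to these spots cannot be told from one of the genes here. The Prxl2c mean was -0.41 without the 6 h array.

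None of these genes passed limma's moderated test at an adjusted p under 0.05. The count was 0 of 8552 genes with a value on all 4 arrays, and the lowest adjusted p, for Mrps24 and 3110082I17Rik, was 0.0608. Without adjustment, 973 genes had a p under 0.05, 364 positive and 609 negative, where 427.6 would be expected by chance if the arrays were independent. Among the named genes, the adjusted p was 0.287 for Cacna1b, 0.294 for Pou3f4, 0.379 for Fbln2 and 0.416 for Car1. The sign was the same on all 4 arrays for 1867 genes (860 positive, 1007 negative), or 21.8%, against 12.5% for independent signs. With weights per array the same model called Mrps24 and 3110082I17Rik.

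Of the 27 fixed lists, the markers of CA3 pyramidal neurons, the field that projects to CA1, had lower log ratios than other genes in the mean over times. Of 8 tested, 7 were negative, with a list median of -0.21. Nectin3, an adhesion gene, had a mean of -0.36 and was negative on all 4 arrays, Plagl1, an imprinted transcription factor gene, was at -0.40, Iyd at -0.25 and the RNA-binding protein gene Elavl2 at -0.24. camera with its preset correlation gave an adjusted p of 0.00598 over the 27 lists. The adjusted p was 0.997 with an estimated correlation (unadjusted p 0.0451), and fry, which tests the list against no change and not against other genes, gave an adjusted p of 0.252. At the level of genes, 1 CA3 marker, Nectin3, passed when adjusted over the list alone and 0 over all genes, with 4 at an unadjusted limma p under 0.05. Of the genes named above, only Nectin3 was among those 4. The unadjusted limma p was 0.074 for Plagl1, 0.059 for Iyd and 0.094 for Elavl2. Elsewhere 1 gene of the circadian clock list (Csnk1d) and 1 of the choroid plexus list (Kl) passed when adjusted over the list alone, and 0 in each of the other lists. Csnk1d had a positive mean of 0.27 on 1 spot. The Kl mean of -0.26 rested on 1 of 3 spots, and was 0.048 with the median of its spots. Without the 4 h array camera's adjusted p was 0.1002. The Plagl1 mean rested mainly on 1 of its 2 spots, which gave -2.19 at 6 h, and was -0.15 without that array. The Iyd mean was -0.16 without the 2 h array and -0.37 without the 6 h array, and the Elavl2 mean -0.14 without the 4 h array and -0.39 without the 1 h array. Nectin3 had 4 spots, 1 of them at -1.28, -1.33 and -1.29 at 1, 2 and 4 h, and the others between -0.27 and 0.21 at those times.

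Endothelial and mural markers had a negative mean in 13 of 19 genes with a median of -0.086, and did not pass (camera's adjusted p 0.199). Cldn5 was at -0.35, Slco1a4 at -0.30, Kdr at -0.30 and the smooth muscle gene Tagln at -0.17. Without the 2 h array the Cldn5 mean was -0.20, and without the 6 h array the Kdr mean was -0.19. Without the 6 h array the list passed with camera's preset correlation at an adjusted p of 0.00189, but the adjusted p was 0.967 with an estimated correlation (unadjusted p 0.0538). Astrocyte markers, with Glul at 0.20 and Slc1a3 at -0.14, had a median of 0.045 (adjusted p 0.199). Microglia markers, with Fcer1g at 0.20 and C1qb at 0.17, had a median of 0.046 (adjusted p 0.258). Immediate early genes had a median of 0.015 (adjusted p 0.534), with Egr2 at 0.32, Srf at 0.27, Arc at 0.22 and Klf4 at -0.22. The Egr2 mean was 0.14 without the 6 h array and 0.49 without the 1 h array, the Arc mean 0.12 without the 4 h array and 0.36 without the 1 h array, and the Klf4 mean -0.14 without the 1 h array. The Glul mean was 0.096 without the 4 h array and 0.30 without the 1 h array, and the Slc1a3 mean -0.083 without the 4 h array and -0.22 without the 6 h array. In the immediate early gene list 0 genes passed when adjusted over the list alone, 0 over all genes, and 2 had an unadjusted limma p under 0.05. Srf was among the latter (limma p 0.0024), while Egr2, Arc and Klf4 were not (0.087, 0.098 and 0.057).

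A slope on hours after the last shock asked for a steady change with time, in which a dye effect shared by the arrays cancels. Ribosomal protein genes had positive slopes in 33 of 39, with a median of 0.029 log units per h, as their medians went from -0.059 and -0.075 at 1 and 2 h to 0.072 and 0.073 at 4 and 6 h. Rpl22 had a slope of 0.11, Rpl8 of 0.078 and Rpl19 of 0.078, while Rps20 had -0.15. Oxidative phosphorylation genes had positive slopes in 35 of 44, with a median of 0.023, among them the cytochrome oxidase gene Cox4i1 at 0.074. The ATP synthase gene Atp5j had 0.14, carried by 1 spot that went from -1.71 at 1 h to -0.15 at 6 h, while its other spot was at 0.11 and 0.10. Cholesterol synthesis genes had positive slopes in 11 of 13, with a median of 0.031, including Msmo1 at 0.076, Idi1 at 0.063 and Sqle at 0.053. Rpl22, Rpl8, Rpl19, Cox4i1, Msmo1 and Idi1 are named after their values were seen.

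These 3 lists rose with time by camera with its preset correlation, with adjusted p of 0.00433 for ribosomal proteins, 0.00494 for oxidative phosphorylation and 0.0345 for cholesterol synthesis. With an estimated correlation the adjusted p was 0.883 for each, and fry's test of the list alone gave 0.559 for each. Adjusted over the list alone, 0 genes of each of these lists passed, and 0 over all genes, while 4 ribosomal, 3 oxidative phosphorylation and 0 cholesterol synthesis genes had an unadjusted limma p under 0.05. Among the other lists, 2 NF-kB targets and signalling genes passed when adjusted over the list alone, the cytokine Il6 with a slope of -0.13 and the adaptor Traf2 with -0.12. The Traf2 slope was carried by 1 spot that went from 0.42 at 1 h to -1.08 at 6 h, while another went from 0.0076 to 0.0998. Without the 1 h array the adjusted p was 0.130 for oxidative phosphorylation and 0.597 for cholesterol synthesis, and the latter was also lost without the 4 h array (0.0540) and without the 6 h array (0.155).

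Single genes with the steepest positive slopes by moderated t were the small GTPase Arf6 (0.20 per h), Clps (0.17), Pla2g2e (0.17) and the sphingolipid enzyme Kdsr (0.16). The most negative were Crisp3 (-0.27), the prostacyclin synthase Ptgis (-0.25), Lce1a2 (-0.36) and the heparan sulfate proteoglycan Sdc1 (-0.24). Arf6 went from -0.72 at 1 h to 0.31 at 6 h, and Sdc1 from 0.083 to -1.13. No slope passed limma's adjusted p of 0.05, with 0 of 8552 genes and a lowest adjusted p of 0.106. Without adjustment 1250 genes had a limma p under 0.05, 397 positive and 853 negative. That count was 693 without the 6 h array, whose spread was wider, and 715 with quantile normalization between arrays. It was 863 with array weights and 918 with arrays scaled to the same median absolute deviation. Without the 1 h array it was 1330, and without the 4 h array 1452. Without the 4 h array 418 genes passed after adjustment, with fewer arrays behind the error.

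The 4 arrays were compared across genes to see how alike the times were. The 2, 4 and 6 h arrays resembled each other, with Pearson correlations across 8552 genes of 0.334 for 2 and 4 h, 0.341 for 4 and 6 h and 0.220 for 2 and 6 h. The 1 h array correlated with the 2 h array at 0.167, and at -0.0193 and -0.0075 with the 4 and 6 h arrays. Genes are not independent replicates, and arrays of 1 dye orientation share dye effects. Among 2695 genes with several spots, the 2, 4 and 6 h arrays correlated at a mean of 0.260 when the same spot was taken on both arrays. The mean was 0.0313 when a gene was represented by different spots on the 2 arrays.

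**Figure D3:**
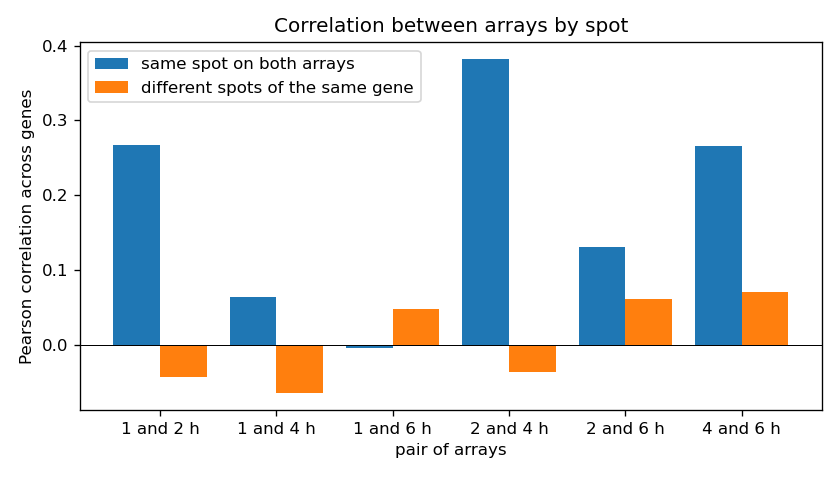
Pearson correlation across genes (vertical axis, bars from 0) for the 6 pairs of arrays (horizontal axis), in genes with several spots. Blue bars take the same spot on both arrays and orange bars different spots of the same gene. For 2 and 4 h the values were 0.382 and -0.0370.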

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

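The tests on other abundant transcripts and on the slope without the 1 h array were chosen only after the slopes had been seen. Ribosomal protein genes, which build the translation machinery, had a median 0.147 log units higher at 4 h than at 2 h, from -0.075 to 0.072, a difference that was not tested. Oxidative phosphorylation genes moved by 0.130 between the same arrays, from -0.071 to 0.059, also not tested. Immediate early genes had a median 0.167 higher at 4 h than at 1 h, from -0.087 to 0.080, not tested either. In the list test of the slope, which compares times, the median slope per h was 0.0293 for ribosomal proteins, 0.0233 for oxidative phosphorylation and 0.0312 for cholesterol synthesis. Their adjusted p with camera's preset correlation was 0.00433, 0.00494 and 0.0345, and 0.883 for each with an estimated correlation.

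The common positive slope of ribosomal and respiratory chain genes was weighed further, since these lists hold the most abundant transcripts of a cell. The 1 h array alone is argued against as the source of the size of these slopes. With it the median was 0.0293 per h for 39 ribosomal genes and 0.0233 for 44 respiratory chain genes. Without it the median was 0.0312 for 48 ribosomal genes (95% bootstrap interval over genes 0.0197 to 0.0487) and 0.0235 for 45 respiratory chain genes (0.0130 to 0.0383). The gene sets thus differed somewhat, and these intervals treat genes as independent, which they are not. Without the 1 h array camera's call was lost for the respiratory chain (adjusted p 0.130) and kept for ribosomal proteins (0.0371). An intensity-dependent dye effect could move all abundant transcripts alike. The median slope of 45 other abundant brain transcripts, among them Gapdh, Eno2 and Camk2a, was 0.00425 (95% interval -0.00595 to 0.0137, percentile 86.9 of random lists), against 0.0249 for 83 genes of both lists, and the upper end of that interval leaves such an effect open. A response to conditioning under MK-801 stays open too and was not tested, since each time has 1 array.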

How the results depend on the processing

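Settings added after the data were seen are the base-2 and natural log readings, exact zeros kept, the running median over neighbouring spots, camera on ranks and fry for the slope, the median of a gene's spots for lists, estimated correlations for lists added elsewhere, and named gene means without each array. At 1, 2, 4 and 6 h the count of genes past the size threshold was 2299, 2457, 2377 and 4029 at 1.5-fold and 226, 176, 178 and 1091 at 3-fold. It was 76, 101, 74 and 375 among genes with 2 or more spots, 22, 23, 23 and 93 with base-2 logs, and 69, 59, 65 and 438 with natural logs. At 2 h it was 1016 with each spot on its own. The positive share at 6 h was 34.2% among genes measured on all 4 arrays. In the mean, limma called 2 genes at an adjusted p under 0.10, 2 with array weights and 2 without genes under 0.3 log2 on all arrays, each time Mrps24 and 3110082I17Rik. It called 1, Map3k7, with a value on at least 3 arrays, and 0 to 1 leaving out each array in turn (Map3k7 without the 4 h array). For the slope it called 100 without genes under 0.3 log2, and 0 to 418 leaving out each array, with 418 without the 4 h array. The filter at 0.3 log2 selects genes by the ratios being tested, so its counts do not bear on how stable the results are.

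In the mean, 0 lists were called with an estimated correlation, 0 with fry, and 0 to 2 leaving out each array, with 0 without the 4 h array and endothelial markers added without the 6 h array. For the slope, 0 lists were called with an estimated correlation, 0 with fry, and 2 to 4 leaving out each array. Lists added there were choroid plexus markers (negative, adjusted p 0.0150 without the 2 h array and 0.0225 without the 6 h array), immediate early genes (positive, 0.0151 without the 6 h array) and heat shock genes (negative, 0.0371 without the 1 h array). Choroid plexus markers also passed with the median of a gene's spots (0.0356), and endothelial markers with the running median removed (positive, 0.0304). With an estimated correlation under the same settings none of these lists passed, with a lowest adjusted p of 0.826. The mean correlation of the 6 pairs of arrays was 0.142 without genes past 2-fold on any array, against 0.172. Of 107 alternatives of the main results 72 kept their value within the limits set, and of 37 alternatives of called lists 24 kept their call, 13 lost it and 0 reversed. With the median of a gene's spots and with values not centred, named gene values moved in 2 of 388 alternatives, both with the median, Nectin3 to -0.22 and Kl to 0.048. These settings could move few values and do not show that the others are stable. Mean and median are equal for genes with 1 or 2 spots, and centring shifted an array by at most 0.0055. Leaving out each array in turn, the means of 91 of 162 named genes moved by over 1.5 times at least once, 23 of them with a turn in sign. The cause was not tested, except that fewer genes enter under filters and higher thresholds. The planned filter on dim spots was not run, as no intensities were used, so what signal over background limits is unknown.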

Other observations

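The tests of different spots of a gene, of meninges, of 2-fold counts in the choroid plexus and leptomeningeal lists, of genes with several spots past 2-fold, of the signs of the arrays and of named gene means without single arrays were chosen only after the results had been seen. Neuronal gene groups other than those above stayed near 0 in the mean over times. Presynaptic vesicle genes were negative in 17 of 23, with a median of -0.039 (camera's adjusted p 0.534), led by Vamp1 at -0.55, the fusion ATPase Nsf at -0.17 and the calcium sensor Syt1 at -0.16. Glutamate receptor and postsynaptic density genes had a median of -0.0017 (adjusted p 0.987), with the synaptic exchange factor gene Kalrn at 0.27 and the AMPA receptor gene Gria3 at -0.25. GABA synthesis and receptor genes were at -0.011 (0.987), with Gabrg3 at 0.14. CREB, PKA and MAPK signalling genes were at -0.018 (0.996), with Atf1 at 0.18, and late activity-regulated plasticity genes at -0.0070 (0.987), with the activin gene Inhba at 0.29 and the BDNF receptor gene Ntrk2 at -0.24. Cytoskeleton and adhesion genes were at 0.015 (0.877), with Stmn2 at -0.18, and chromatin modifiers at -0.013 (0.996), with Smarcc1 at -0.19. Some of these gene means rested on 1 array. Without the 4 h array Vamp1 was at -0.14, without the 6 h array Kalrn was at 0.12, Gabrg3 at 0.085 and Ntrk2 at -0.098, and without the 1 h array Ntrk2 was at -0.45.

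Stress and housekeeping groups gave similar values. Glucocorticoid-responsive genes had a median of 0.0053 (adjusted p 0.543), with Glul at 0.20 and Tsc22d3 at 0.16. Circadian clock genes were at 0.0049 (0.877), with the kinase gene Csnk1d at 0.27. NF-kB family members and targets were at -0.0066 (0.987), with the chemokine Cxcl1 at -0.23, heat shock genes at -0.018 (0.996), with Hspa1b at -0.24, and proteasome subunits at -0.026 (0.534), with Psmd13 at -0.22. Ribosomal proteins, oxidative phosphorylation and cholesterol synthesis were at -0.0062 (0.987), -0.025 (0.996) and 0.025 (0.987). Among cell type markers, CA1 pyramidal cells were at -0.053 (0.938), with 5 of 6 genes negative, among them Ndst4 at -0.15. Wfs1, at 0.21, was the 1 positive CA1 marker. Dentate granule cells were at 0.057 (0.833), with Prox1 at 0.14, and interneurons at 0.021 (0.987), with Pvalb at -0.11. Oligodendrocytes and myelin were at -0.016 (0.996), with Mog at -0.12, thalamus and neocortex at -0.022 (0.996), with Tbr1 at -0.13, blood at -0.093 (0.718), with Hba-a1 at -0.10, and choroid plexus and ependyma at 0.14 (0.534). The choroid plexus and ependyma value rested mainly on the 1 h array. Its list median was 0.47 at 1 h and 0.013, -0.017 and -0.11 at 2, 4 and 6 h. Without the 6 h array the means of Prox1, Mog and Hba-a1 were 0.051, -0.048 and -0.039. Glul was at 0.096 without the 4 h array, Cxcl1 at -0.13 without the 2 h array and Hspa1b at -0.11 without the 1 h array. Without the 1 h array Glul was at 0.30 and Hba-a1 at -0.17, and without the 2 h array Hspa1b was at -0.37. Spots of Hspa1b, Cxcl1, Mog, Hba-a1 and Gabrg3 differed in sign at 1 or more times.

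The positive log ratios of choroid plexus genes at 1 h may come from choroid plexus tissue in 1 of the RNA samples of that array, since this tissue lies against the hippocampus. In a further list of 36 choroid plexus genes, of which 0 are in the other fixed lists, 22 were measured at 1 h and 13 were positive. The list median of 0.072 was at percentile 96.9 of random lists, close to the upper bound of 0.0761, so it neither passed nor fell clearly below. Its median was at percentile 38.2 at 2 h, 95.7 at 4 h and 96.3 at 6 h, so a high median was not particular to 1 h. Clic3 (0.73), Pcolce2 (0.67), Cdkn1c (0.55), Lbp (0.54), Cltrn (0.41) and Perp (0.33) passed 2-fold at 1 h, as many as in 0.08% of random lists. At 2, 4 and 6 h, 1, 1 and 3 genes of the list did so, as many as in 47%, 50% and 52%. Ependyma is argued against, with 13 further cilia genes at percentile 45.7 and none past 2-fold, while 21 leptomeningeal genes at percentile 36.3, with 3 past 2-fold (Ogn, Mgp and Foxc1), as many as in 8.81% of random lists, do not settle the part of meninges. A response of these genes to conditioning was not tested, Ttr had no ratio at 1 h, and ratios do not tell how many of these genes CA1 itself expresses.

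The correlation of the 2, 4 and 6 h arrays could reflect effects tied to spots, such as dye or position, more than to genes. It fell from 0.260 (95% bootstrap interval 0.232 to 0.287) with the same spot to 0.0313 (0.0104 to 0.0548) with different spots of a gene, a difference of 0.229 (0.193 to 0.262). Spots of a gene that detect different transcripts or are assigned to the wrong gene would give the same fall, so these cannot be separated here. A smooth trend along the spot numbers is argued against, since the mean correlation of the 3 pairs was 0.295 after a running median over 51 neighbouring spots was removed and 0.298 before. How spot numbers map to places on the array was not known here, so other effects of position stay open. Neighbouring spots did correlate within arrays (Spearman 0.209, 0.172, 0.161 and 0.259 at 1, 2, 4 and 6 h), and a lasting response to conditioning stays open and untested.

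In the mean over times, 973 genes had an unadjusted p under 0.05. Turning the signs of single arrays gives 8 patterns, the real one included, and 1 of them, the real one, reached that count. The highest other pattern, with the 1 h array turned, had 725 genes. With 8 patterns no share under 0.05 can be reached.

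Some genes with several spots gave the same sign in each past 2-fold. Hpca, a neuronal calcium sensor gene of the hippocampus, and Arf5, a small GTPase gene, were negative at 1 h and positive at 4 h in all their spots, and Arf5 was also negative at 2 h. There were 14 such genes at 1 h, 12 at 2 h and 13 at 4 h, against 7.04, 10.2 and 6.55 after shuffling spots among genes. As many were reached in 10, 317 and 12 of 1000 shuffles, so the 2 h count, which includes Arf5, did not stand out from shuffled spots. The genes were picked after their values were seen.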
